A study of Rattus norvegicus with 2 samples.

How the data were processed

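Total RNA from rat lung was measured on 2 Affymetrix Rat Genome 230 2.0 arrays, short-oligonucleotide arrays on which each probe set is a group of probes, mostly near the 3' end of a transcript. Per the labels, each array was handled by a different experimenter, RNA was purified on silica columns and cRNA was labelled with biotin by the array maker's protocol. The 2 arrays are called the array of experimenter 1 and the array of experimenter 2, in the order of the numbers in their titles. The labels do not state the strain, sex or number of animals, any treatment, or whether both experimenters started from the same lung or the same RNA.

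The deposited values were made by the authors with RMA (robust multi-array average), per the submitters' processing notes. RMA corrects the background, forces the arrays' probe intensities to a common distribution and summarises the probes of each probe set into 1 value. Its version, its annotation and the set of arrays normalized together are not given in the sources used here. The log base is not stated either and was taken as 2 from the range of the values. RMA gives no detection calls, so a low value has no stated background limit, and its common distribution hides any difference in total RNA between arrays. Scanner files were not used here.

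The table held 31099 probe sets, of which 57 were controls and were kept apart. Of the other 31042, 20826 had 1 gene symbol in the platform annotation, 436 had several and 9780 had none. Entrez identifiers were matched to the gene table of rat assembly GRCr8 to update symbols, which gave a current symbol for 20758 of the 20826; the others kept the annotation's symbol. No probe set with several symbols was named. No genomic coordinates are given, because the build behind the probe design is not stated in the sources used here.

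All differences are the value of experimenter 2 minus that of experimenter 1, on the log2 scale of the deposited values, with no further centring unless stated. A gene was represented by its probe set with the highest mean over both arrays, which gave 14217 genes. With 1 array per experimenter there is no replicate error, and no p-value, standard error or call of a changed gene can be made. A fixed rule of size took their place: a gene was counted when its difference was at least 2-fold (1 on the log2 scale) and its mean was at or above the median of all probe sets, which left 9558 genes. The number of arrays, not the number of probe sets, limits the precision.

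Before the data were examined, 40 gene lists were fixed: 13 of lung cell types, 10 of blood and neighbouring tissues, 15 of responses or cell states, 1 of sex-linked genes and 1 of common reference genes. Each list's median difference was placed among 10000 random lists of the same size, matched on mean level in 20 bins. A list was said to stand apart when it lay outside the central 95% of its random lists. The percentile describes these 2 arrays and is no p-value, since genes of a list vary together; about 5% of lists stand apart by chance.

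The genes named were also chosen by a rule fixed before the data were examined: up to 15 genes with the largest differences in each direction among those counted, up to 4 members of each list that stood apart with the largest differences in the direction of its median, the member with the highest mean of each other lung cell type list, and the sex-linked genes. For genes with at least 2 probe sets, the difference of the brightest probe set was compared with that of the second brightest. Intervals of that correlation are 95% bootstrap intervals from 1000 resamples of genes; they cover the sampling of genes, not of arrays.

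The alternatives were median centring, removal of a loess trend (fraction 0.3), quantile normalization of the 2 columns, other filters on level, a 1.5-fold threshold, the mean over a gene's probe sets, the second brightest probe set, and the mean in place of the median of a list. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots used matplotlib 3.10.9. The scripts were tested on simulated data. With normal noise of the observed SD and 200 genes changed by 1.5 on the log2 scale among the 9558, 96.5% of the changed genes and 4 unchanged genes passed the 2-fold rule. This noise had the same SD at all levels and no skew, whereas the observed differences had a skew of 0.32 and an SD that varied with level. The 4 is therefore no estimate of how many genes pass by noise in the data. Gene differences shared by all probe sets, simulated with an SD of 0.2 over 4525 genes, gave a correlation of 0.356 between probe sets and were recovered as an SD of 0.204.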

Results

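Gene expression in rat lung was profiled on 2 arrays, 1 prepared by each of 2 experimenters, to ask how reproducible global expression values are. Each array gave log2 RMA values for 31042 probe sets besides the controls. The values of experimenter 1 ran from 2.31 to 14.51 with a median of 6.32, and those of experimenter 2 ran from 2.26 to 14.49 with a median of 6.28. There were no replicate arrays within an experimenter, so all differences below are between 2 single arrays and none has a replicate error.

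Of the brightest markers of the 13 lung cell types listed, 5 differed by under 0.1 between the arrays and 8 by more, up to -0.44 for *S100a9*. *Sftpc*, the surfactant protein of alveolar type 2 cells, measured 14.39 and 14.36 for experimenters 1 and 2. *Scgb1a1*, the secretoglobin of club cells, measured 14.37 and 14.44, and *Lyz2*, a lysozyme gene of macrophages, measured 14.51 and 14.49. These values lie at the top of each array's range, and other lung cell markers, named after their values were seen, differed more: *Gpm6a* of the mesothelial list by 0.85, *Calcrl* and *Tie1* of the endothelial list by -0.74 and -0.55, and *Rsph1* of the ciliated cell list by 0.51. Over all 31042 probe sets the values correlated with Pearson's r = 0.993 and Spearman's rho = 0.992, across probe sets, which are not independent replicates. The difference had a median of -0.052 and an SD of 0.28 on the log2 scale, and 95.6% of probe sets agreed within 1.5-fold. The SD of the difference was 0.21 for means up to 3.41, was highest at 0.32 for means between 4.76 and 5.52, and was 0.23 for means from 9.58 up, when probe sets were put in 10 bins by mean.

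Of the 9558 genes compared, 25 were at least 2-fold higher on the array of experimenter 2 and 2 were at least 2-fold lower, together 0.282%. The largest difference was that of *Nsmce3*, a subunit of the SMC5/6 DNA repair complex, at 6.23 for experimenter 1 and 8.001 for experimenter 2, which is 3.42-fold. *Slk*, a STE20-like protein kinase, was 2.66-fold higher for experimenter 2, *Smc2*, a condensin subunit, 2.63-fold, *Klhl2*, a kelch-like adaptor of a ubiquitin ligase, 2.59-fold, and *Osbpl3*, an oxysterol-binding protein, 2.43-fold. The other genes among the 15 with the largest positive differences were *Znrf3*, a ubiquitin ligase acting on Wnt receptors, *Chic1*, *Snx10*, a sorting nexin, *Slbp*, the histone stem-loop binding protein, *Ift81*, an intraflagellar transport protein, *Rbl1*, a retinoblastoma family protein, *Ly75*, an endocytic receptor of dendritic cells, *Rhno1*, *Rab21*, an endosomal GTPase, and *Klhl9*, with folds from 2.37 down to 2.12. The 2 genes at least 2-fold lower for experimenter 2 were *Pcf11*, a factor of mRNA 3' end cleavage and transcription termination, at 8.80 against 7.58, and *Taok1*, a protein kinase, at 8.52 against 7.41. The values of *Nsmce3*, *Rhno1*, *Snx10* and *Slbp* came from probe sets whose identifiers mark probes shared between transcripts, which for *Nsmce3* and *Rhno1* are those of a single gene. None of the 566 distinct genes measured in the 40 fixed lists was 2-fold apart.

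**Figure D1:**
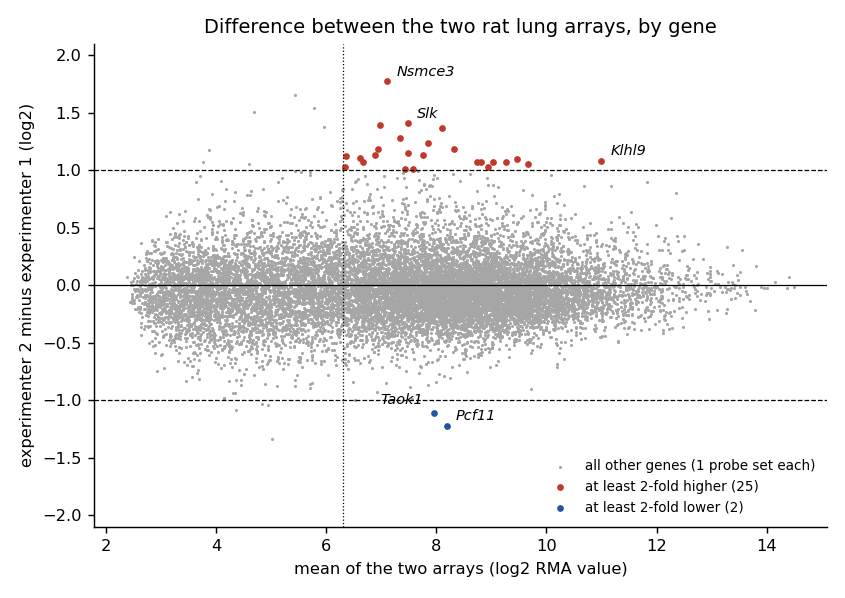
Difference between the arrays (experimenter 2 minus experimenter 1, log2) against the mean of both (log2 RMA value) for 14217 genes, 1 point per gene. Dashed lines mark 2-fold and the dotted line marks the median of all probe sets; 25 genes to its right lie above the upper line and 2 below the lower line, while grey points left of it were not counted.

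A second probe set of the same gene did not repeat these differences. Of the 27 genes past 2-fold, 14 had another probe set. It differed in the same direction for 5 and in the opposite direction for 9, and for 0 of the 14 did it reach 2-fold. Of these second probe sets, 9 had means at or above the median of all probe sets. That of *Slbp* had a mean of 2.85, near the lowest mean of all (2.36), where a difference may not show. *Slk* differed by 1.41 by its brightest probe set and by -0.76 by its second (6.71 and 5.95). *Ift81* differed by 1.14 and -0.66, *Snx10* by 1.18 and -0.40, and *Osbpl3* by 1.28 and -0.27, while *Nsmce3* had 1.77 and 0.093 and *Klhl2* 1.37 and 0.27. For *Pcf11* the brightest probe set differed by -1.22 and the second by 0.33. Over all 4525 genes with at least 2 probe sets, the differences of the brightest and the second correlated across genes with Pearson's r = 0.027 (95% bootstrap interval -0.0065 to 0.057) and Spearman's rho = 0.035. The mean levels of the same pairs correlated with r = 0.689. Sorting each pair by level makes such a correlation positive by itself, so this value alone does not measure agreement between probe sets.

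**Figure D2:**
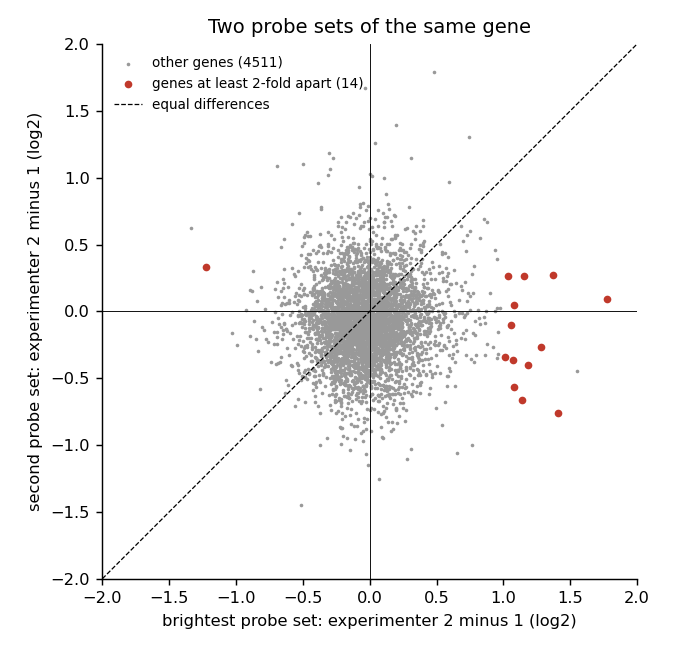
Difference between the arrays (experimenter 2 minus experimenter 1, log2) by the second brightest probe set of a gene against that by its brightest, 1 point for each of 4525 genes; the dashed line marks equal differences. The 14 genes past 2-fold lie away from that line, and the cloud has r = 0.027.

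Among the 13 lists of lung cell types, each median lay inside the central 95% of its matched random lists. The epithelial lists had medians of -0.066 for alveolar type 2 cells (11 genes measured), -0.075 for alveolar type 1 cells (11), -0.15 for club and secretory cells (10) and -0.17 for ciliated cells (10). The brightest alveolar type 1 member, *Hopx*, a homeodomain-only protein, measured 13.11 and 13.44, and *Tppp3*, a tubulin-binding protein of ciliated cells, 12.22 and 12.05. Medians were -0.13 for endothelial cells (14 genes), -0.060 for fibroblasts and matrix (15), -0.11 for smooth muscle and pericytes (14) and -0.028 for mesothelial cells (10). *Ramp2*, the co-receptor for adrenomedullin, measured 12.47 and 12.48, *Mfap4*, a microfibril-associated protein, 13.39 and 13.15, *Tagln*, the smooth muscle protein transgelin, 11.71 and 11.61, and *Krt19*, a keratin, 11.91 and 11.52. Among leukocytes the medians were -0.15 for macrophages (11), -0.011 for neutrophils (11), -0.11 for T and NK cells (19), 0.12 for B and plasma cells (11) and 0.015 for mast cells and basophils (12). *S100a9*, a calgranulin of neutrophils, measured 11.28 and 10.84, *Prf1*, perforin of cytotoxic cells, 10.31 and 10.24, *Jchain*, the joining chain of polymeric immunoglobulins, 11.16 and 11.34, and *Mcpt1*, a mast cell protease, 7.57 and 7.37. The B and plasma cell list, with 7 of 11 members higher for experimenter 2, was at percentile 97.4, next to the bound, and passed it under 3 alternatives. Endothelial cells fell past their lower bound under 3 alternatives, and T and NK cells did so with genes at or above the median level alone, where their median was -0.25.

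Lists for blood and for tissues that a lung sample can carry along held the 2 lists that stood apart downward. Peripheral nerve genes had a median of -0.29 (9 genes, percentile 0.295) and were lower for experimenter 2 in 6 of 9. *Sox10*, a transcription factor of Schwann cells, measured 5.82 and 5.16, *Nefm*, the medium neurofilament chain, 3.85 and 3.19, *Mbp*, myelin basic protein, 9.11 and 8.51, and *Mal*, the myelin and lymphocyte protein, 8.49 and 8.03. The 3 nerve members that were higher, which the naming rule passes over, were *Nefl* (2.91 and 3.28), *Pmp22* (12.04 and 12.07) and *Gap43* (3.31 and 3.33). Liver genes had a median of -0.24 (14 genes, percentile 0.69) and 13 of 14 were lower. *Apoa2*, an apolipoprotein, measured 5.24 and 4.82, *Alb*, albumin, 5.41 and 5.04, *Serpina1*, alpha-1-antitrypsin, 7.00 and 6.66, and *Tat*, tyrosine aminotransferase, 3.54 and 3.20. Only 4 of the 9 nerve genes and fewer than 3 of the liver genes had means at or above the median of all probe sets. The other medians in this group were -0.087 for red cells and reticulocytes, -0.043 for platelets, -0.11 for cardiac muscle, -0.031 for skeletal muscle, -0.20 for adipose tissue (percentile 2.5, on the bound), -0.19 for cartilage, -0.020 for thymus and lymph node and -0.0038 for oesophagus and squamous epithelium.

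Each of the 15 response and state lists lay inside the central 95% of its random lists. Medians above 0 were those of cell cycle genes at 0.072 (15 of 25 higher), immediate early genes at 0.045 (14 of 24 higher; outside the band by the list's mean of 0.081), cholesterol and fatty acid synthesis at 0.014 and the glucocorticoid response at 0.0085. The others were -0.010 for ribosomal proteins, -0.023 for the circadian clock, -0.035 for the type 2 and allergic response, -0.055 for inflammation, -0.061 for the mitochondrial respiratory chain, -0.076 for heat shock, -0.095 for hypoxia, -0.098 for antigen presentation by MHC class II, -0.11 for the xenobiotic and oxidative response, -0.11 for the interferon response and -0.14 for endoplasmic reticulum stress. Common reference genes had a median of -0.11, with 9 of 11 lower for experimenter 2.

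Sex-linked genes were the 1 list that stood apart upward, with a median of 0.24 over 6 genes (percentile 99.5). The list mixes Y-linked and X-linked genes, so its median cannot show a difference in sex. The Y-linked *Eif2s3y*, a translation initiation factor subunit, measured 8.86 for experimenter 1 and 9.25 for experimenter 2, and the Y-linked *Uty* 8.91 and 9.20. Of the X-linked members, *Kdm5c*, a histone demethylase, measured 7.71 and 8.02, and *Eif2s3*, the relative of *Eif2s3y*, 9.002 and 9.20. *Kdm5c* and *Uty* differed by -0.36 and -0.067 by their second probe sets. *Xist*, the RNA of X inactivation, measured 3.34 and 3.01, and *Sry* 4.79 and 4.67. On both arrays *Eif2s3y* and *Uty*, by their brightest probe sets, lay above that array's median. *Xist* lay below the lower quartile of both arrays (4.42 and 4.37), so these 3 genes had the same pattern on each. The list lay inside the band by its mean difference of 0.12 (percentile 94.2), by its median of 0.057 with the mean over probe sets (percentile 87.8) and by its median of -0.089 with the second brightest probe sets (percentile 39.8), so its place outside depended on the brightest probe set and on the median. Over all 40 lists, 3 stood apart, against 2 expected by chance.

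**Figure D3:**
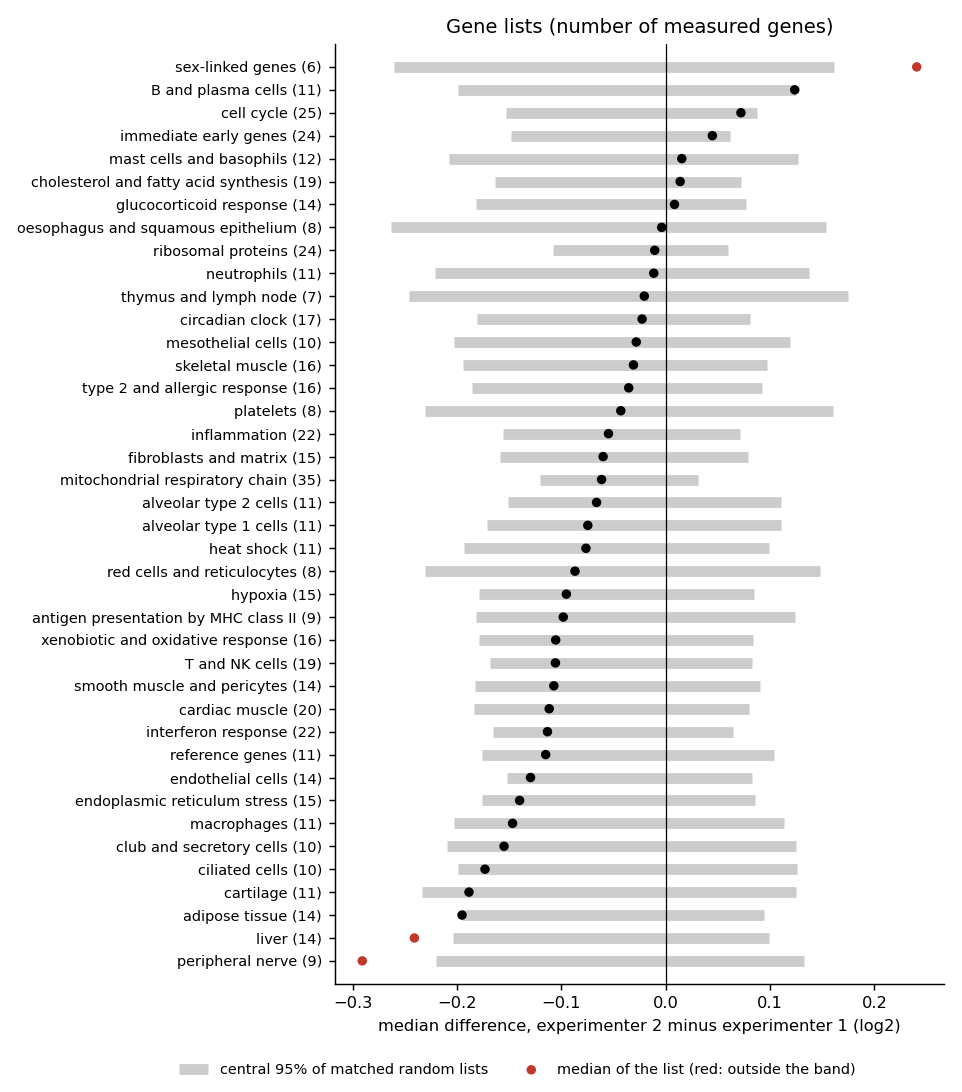
Median difference (experimenter 2 minus experimenter 1, log2) of each of 40 gene lists, as points, with the number of measured genes after the name; grey bars span the central 95% of 10000 matched random lists. The red points, peripheral nerve at -0.29, liver at -0.24 and sex-linked genes at 0.24, lie outside their bars.

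Control probe sets described the RNA and the labelling of each array. The gap between the 3' and the 5' probe sets of *Actb*, beta-actin, which grows when labelled RNA is shortened, was 2.15 for experimenter 1 and 2.71 for experimenter 2. The gap of *Gapdh*, a glycolytic enzyme, was 0.30 and 0.26, and that of *Hk1*, a hexokinase, 1.13 and 1.36. Among the poly-A spike-in transcripts it was 3.32 and 3.95 for dap, 0.63 and 0.19 for lys, 1.87 and 2.03 for phe and 4.41 and 4.42 for thr. These are from the newer of the probe set designs on the array; the older design of the same spike-ins gave 3.58 and 3.99 for dap, 2.67 and 2.65 for lys, 2.06 and 1.73 for phe and 3.53 and 3.76 for thr, so the direction for phe depended on the design. The hybridization spike-ins had mean levels by the newer design of 8.43 and 8.3997 for bioB, 10.0003 and 10.02 for bioC, 12.28 and 12.18 for bioD and 13.65 and 13.88 for cre, and by the older design of 8.38 and 8.23, 9.89 and 9.66, 11.34 and 11.21, and 13.33 and 13.42. Over both designs the median difference was -0.015 over the 18 hybridization probe sets and 0.091 over the 24 poly-A probe sets, of which 16 were higher for experimenter 2.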

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

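The second brightest probe set as an alternative for the gene lists was chosen after seeing the data. No paired analysis was possible because each experimenter has 1 array, and for the same reason no array could be left out. Centring, loess and quantile normalization gave 30 to 33 genes higher and 2 lower. Restricting the agreement to probe sets at or above the median level, or to the upper 25%, gave r of 0.983 and 0.976, an SD of 0.27 and 0.24, and 96.1% and 97.5003% of probe sets within 1.5-fold; the narrower range of levels accounts for the lower r. The counts of genes higher and lower were 33 and 6 with no filter on level, 9 and 0 in the upper 25%, 189 and 78 at 1.5-fold, 14 and 1 with the mean over probe sets, and 21 and 4 with the second brightest probe set. Of the 27 genes counted, 13 had 1 probe set and passed unchanged under both probe set choices; the second probe sets themselves gave 9 and 3, and 0 of the other 14 genes kept 2-fold by them. By second probe sets at or above the median level, the direction turned for *Slk* (-0.76), *Osbpl3* (-0.27), *Snx10* (-0.40) and *Pcf11* (0.33) among the 17 genes named by the rule, and for *Vma21* (-0.34), *Rc3h2* (-0.099) and *Ikzf5* (-0.36) among the others counted. The cause of these turns was not tested here. The number of lists standing apart was 5 after loess, which added B and plasma cells and adipose tissue, and 3 or 4 under the other alternatives. B and plasma cells also stood apart after quantile normalization and with the mean over probe sets, and endothelial cells under 3 alternatives: both probe set choices and the mean of a list. T and NK cells stood apart with genes at or above the median level (-0.25), and immediate early genes by the mean of a list (0.081). Peripheral nerve stood apart under all 7 alternatives and liver under the 6 that scored it. Median centring moves a list and its random lists alike, however, so it could not change a percentile. In addition, 5 of 9 nerve genes and 10 of 14 liver genes had 1 probe set, so the probe set choice left them as they were. Sex-linked genes fell inside their band under 3 of the 7: the second probe set (-0.089), the mean over probe sets (0.057) and the mean of a list (0.12). The correlation between probe sets of a gene was 0.014 when both were at or above the median level (2094 genes). Low signal limits the dim lists, since no detection calls were used here.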

Other observations

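Of the tests below, 5 were chosen after the results they concern had been seen; the test on the second probe sets of list members was set before. The largest differences among the 566 list members, named after their values were seen, were those of *Fos*, an immediate early transcription factor, at 0.97, *Gpm6a*, a membrane glycoprotein, at 0.85, *Cxcl2*, a neutrophil chemokine, at 0.82, *Cyp1a2*, a cytochrome P450, at -0.78, and *Calcrl*, the calcitonin receptor-like receptor of endothelium, at -0.74. A second probe set of *Fos* differed by 0.029 at a mean level of 3.85, and one of *Calcrl* by -0.38 at 6.68. *Cxcl2* and *Cyp1a2* had 1 probe set each, at mean levels of 4.64 and 4.69, under the median of all probe sets (6.31). Among probe sets with no symbol or several, 3258 were at or above the median level, of which 11 were at least 2-fold higher and 2 lower.

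More genes were at least 2-fold higher than lower for experimenter 2. An offset left by the normalization would have to raise the array of experimenter 2, but the median difference over all probe sets was -0.052 (95% bootstrap interval -0.055 to -0.049), which argues against it for these 2 arrays. This interval covers the sampling of probe sets, not of arrays. A difference in the RNA level of these genes that every probe set measures is argued against by the second probe sets of the 14 genes that had one: their median difference in the direction of the brightest was -0.30 (95% bootstrap interval -0.40 to 0.093), against a median of 1.14 for their brightest and the bound of 0.57 set for this explanation. For the size of the differences, though not for their direction, differences specific to single probe sets remain a candidate explanation. Over 4525 genes the 2 probe sets correlated with r = 0.027. Most of these genes were not past 2-fold, so that value alone cannot decide for the 14 genes that were. Probe noise and a transcript end that only 1 probe set covers were not separated. Second probe sets too dim to respond remain possible, because no detection calls were used and the median level is no detection limit. For 9 genes past 2-fold the second probe set was at or above the median level, at means from 6.32 (*Ikzf5*) to 8.68 (*Rimoc1*). Of these second probe sets, 7 turned direction and 0 reached 2-fold, but a probe set that does not respond could give the same. Where both probe sets were at or above that level, r was 0.014 (95% bootstrap interval -0.032 to 0.060). That value covers mostly genes not past 2-fold, so it cannot decide for these 9. The excess of higher over lower has no explanation among those tested. It was 9 against 3 among the 2094 second probe sets at or above the median level. Over all 31042 probe sets, at any level, it was 81 against 34.

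The lists that stood apart were few. At least 3 of 40 lists stood apart in 32.3% of 10000 sets of random lists, so chance may account for their number. The sets treat genes as independent, which real lists are not. That share is for the lists as first scored. After loess 5 lists stood apart, and no such share is given for that count. Whether the members' RNA differed cannot be told apart from probe set noise, because only 11 members had a second probe set: its median difference in the direction of the list, after subtracting the median of all second probe sets, was 0.0097 (95% bootstrap interval -0.097 to 0.25), against 0.19 for their brightest, likewise centred on all genes. Without centring these medians were 0.042 and 0.24. Without centring, 4 of the 11 members went with their list by both probe sets compared: 3 of 4 liver genes (*Alb*, *Fgb* and *Cps1*), 1 of 4 nerve genes (*Mbp*) and 0 of 3 sex-linked genes. The labels give no difference between the samples other than the experimenter, and no biological explanation was tested.

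The covariance between 2 probe sets of a gene gives an SD of 0.046 on the log2 scale for differences that both share, against an SD of 0.27 for the brightest probe sets. The shared SD cannot be told from 0, because the 95% bootstrap interval of the correlation spans 0 (-0.0065 to 0.057), and the upper bound of this SD was 0.067. Both values hold for RNA that both probe sets measure, and whether the 2 arrays carried the same RNA is not stated in the labels. They cover all 4525 genes with at least 2 probe sets, at median levels of 8.24 for the brightest and 6.08 for the second. Dim second probe sets could lower both values. With both probe sets at or above the median level (2094 genes), the correlation was 0.014 (95% bootstrap interval -0.032 to 0.060). No shared SD was computed for those genes.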
